A study of Mus musculus with 12 samples.

How the data were processed

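RNA was measured on 12 Affymetrix expression arrays of 45101 probe sets, 3 arrays in each of 4 groups of mice of the same strain: wild-type and Qkf mutant adult dorsal cerebral cortex, and wild-type and Qkf mutant dorsal telencephalon at embryonic day 12.5. Qkf is another name of Kat6b, which encodes a histone acetyltransferase, and the mutants carried a gene-trap insertion on both alleles, per the labels. Total RNA was precipitated from a guanidine hydrochloride solution, amplified over 2 cycles and labelled with biotin, per the labels' protocols. The labels give a mouse number and an age for each adult array (155, 112, and 101 or 99 days) and the parents for each embryonic array. Whether each embryonic array held 1 embryo is not given in the sources used here, and each is called an embryo below.

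The deposited values are log2 expression values, one per probe set and array, and the submitters' processing notes name GCRMA, with no version given in the sources used here. GCRMA is a method that models the background from probe sequence, and its settings and reference set are not given in the sources used here. The lowest value on every array was 2.19, and between 26.3% and 27.6% of the values of an array lay at that floor, so that differences from the floor understate the change. Array medians ran from 3.64 to 3.74. The arrays carry no counts, and the number of arrays limits the precision.

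The values were used as deposited. Probe sets were named through the platform annotation, with symbols brought up to date through the gene ID for 34754 probe sets against the RefSeq annotation of assembly GRCm38.p6, from which only names and the order of neighbouring genes were taken. Of the probe sets, 34945 had exactly 1 gene symbol, 932 had several, 9160 had no gene listed and 64 were controls. Probe sets with 1 symbol were kept where the log2 value was over 4 on at least 3 arrays, which left 20292. For each gene the probe set with the highest mean over all arrays stood for the gene, which gave 11449 genes. Probe sets with several or no listed genes were tested separately and are unnamed here.

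Each gene was fitted with limma (version 3.58.1 in R 4.3.3) using lmFit and eBayes over all 12 arrays, with the 4 groups as means and 8 residual degrees of freedom. The contrasts were mutant minus wild type in each stage, the difference between those 2 contrasts, and adult minus embryonic wild type. P-values were adjusted by Benjamini-Hochberg and a gene was called under an adjusted p of 0.05. All adjusted p-values of genes given below are limma's. Standard errors (SE) are the moderated ones, and group values are means with their SD over 3 arrays.

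Gene lists of complexes, pathways and cell types, 35 in all and including markers of tissues next to the dissected region, were fixed before the data were examined. The 33 lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, against the other genes and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. List means per array were compared by an exact two-sided permutation test, whose smallest p is 0.1 with 3 arrays against 3. The other choices fixed before the data were examined were the tests, the processing alternatives and the rule for naming genes. That rule takes every probe set of the targeted gene. For each mutant contrast it takes the 10 largest rises and 10 largest falls past the test in which every mutant array lies beyond every wild-type array, with open places filled by the lowest p and named as not past the test. It takes 5 each way for the difference between stages and 10 each way for the stages, and for each list up to 4 members with the lowest p. It also takes sex-linked genes and control probe sets per array. Clone-based names were counted and passed over.

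The age pairs and crosses entered only an alternative, as a block. Deviations from the group mean were compared across genes. Such deviations cancel out within a group, so the correlations below are tied to each other and are not separate observations. A positive one for an array forces a negative one with another array of the other genotype. Embryos of the same cross correlated at 0.51 in the first cross and at 0.14 to 0.25 in the second, and embryos of different crosses at -0.36 to -0.23. The pairing of embryos comes from the parents in the labels. The adult age pairs correlated at 0.19, -0.01 and 0.27, and adults of different pairs at -0.30 to 0.23, so that a pairing of the adults by age was not clear.

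Other alternatives varied the filter, the probe sets per gene, the scaling of the arrays, the samples in the fit, array weights, the variance model and each array in turn. Sex as a covariate and a fit without the first cross were added after the data had been seen. Correlations between arrays over all probe sets were 0.994 to 0.997 within adult groups and 0.989 to 0.995 within embryonic groups, and at most 2.84% of the values above the filter were identical between any 2 arrays, so none was taken for a duplicate.

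The fit was tested on simulated data. Values for 11449 genes were drawn from the wild-type means and fitted spreads, with 50 genes changed at each of 4 sizes among those with a wild-type mean over 6. For the adult contrast the fit recovered 24% of the genes changed by a log2 of 0.5, 94% at 1, 98% at 1.5 and 100% at 2. For the embryonic contrast it recovered 18%, 96%, 100% and 96%. Of the calls, 6 of 164 and 7 of 162 were genes that had not been changed. With so many calls the adjusted threshold allowed a higher unadjusted p than in the real contrasts, where 6 and 4 genes were called. The shares recovered therefore likely overstate what the fit could find in the real data. A simulated list shifted in the adult contrast was called, and 0 of 32 unshifted lists were. Noise was drawn for each gene independently, without structure by cross or tissue. The simulation therefore says nothing about false calls that arise from correlation between the genes of a list. No genome build is named for the values, and no coordinates are given.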

Results

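The arrays compared the transcriptome of mice lacking normal function of Kat6b (also called Qkf or Myst4) with wild types at 2 stages, to look for genes whose expression depends on this histone acetyltransferase in the adult dorsal cortex and in the dorsal telencephalon at E12.5. Each of the 4 groups held 3 arrays. All adults were male by label and showed the Y-linked genes Eif2s3y, Kdm5d and Uty without Xist. The sex of the embryos was not labelled. Xist stood at 13.1, 13.1 and 12.7 in wild-type embryos 1 and 2 and mutant embryo 3, and Eif2s3y stood between 9.34 and 9.43 in the other 3 embryos. Female-pattern embryos were thus 2 of 3 wild types and 1 of 3 mutants.

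Kat6b itself, reported first as a check of the labels, fell in the mutants of both stages. In adult cortex its main probe set went from a log2 value of 9.58 ± 0.21 (SD, n = 3) in wild types to 7.11 ± 0.17 (n = 3) in mutants, a 5.54-fold decrease (log2 difference -2.47, SE 0.29, adjusted p = 0.017). In embryonic telencephalon it went from 11.37 ± 0.08 to 7.06 ± 0.77, a 19.8-fold decrease (log2 difference -4.31, adjusted p = 0.00019). Every mutant array lay below every wild-type array in both stages. A second probe set went from 5.02 ± 0.22 to 2.20 ± 0.01 in embryos. In adults that probe set was near the floor in wild types (2.59 ± 0.32) and at the floor of 2.19 in every mutant. The third was at the floor on every array. Where these probes lie relative to the insertion was not determined here. The adult call was lost when any 1 of the 6 adult arrays was left out, with adjusted p between 0.058 and 0.15 and log2 differences between -2.59 and -2.37. It was also lost without a filter on low values (adjusted p = 0.10), as were those of Cartpt, Mxra7 and Ctxn3 below.

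**Figure D1:**
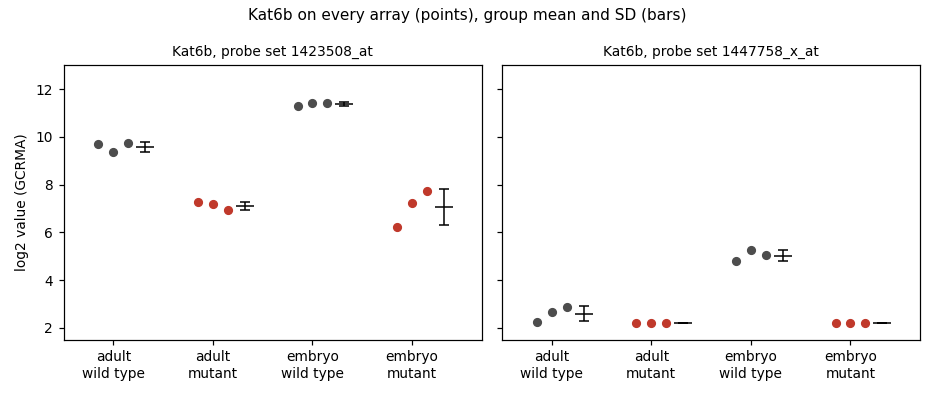
Log2 value (vertical axis) of 2 Kat6b probe sets on each of the 12 arrays (points) in the 4 groups (horizontal axis), with the group mean and SD (bars). With the main probe set the mutants of both stages lie near 7.1, below wild types at 9.58 in adults and 11.37 in embryos.

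In adult mutant cortex 6 genes of 11449 changed, 3 upward and 3 downward. Besides Kat6b, the receptor gene Qrfpr fell 2.79-fold, from 5.59 to 4.12 (log2 difference -1.48, SE 0.16, adjusted p = 0.015), and Ctxn3, which encodes a small membrane protein of the cortexin family, fell from 4.92 to 3.18 (log2 difference -1.74, SE 0.22, adjusted p = 0.027). Cartpt, the precursor of the CART neuropeptides, rose 2.59-fold (log2 4.44 ± 0.47 to 5.82 ± 0.22, n = 3 each, adjusted p = 0.045). Hkdc1, a hexokinase-family gene, rose 2.12-fold (4.58 ± 0.12 to 5.66 ± 0.25, adjusted p = 0.016), and Mxra7 rose 1.80-fold (4.97 ± 0.04 to 5.82 ± 0.19, adjusted p = 0.039). A second probe set of Mxra7 went the other way, and with the mean of its probe sets its log2 difference went from 0.85 to 0.35. Of 24 alternatives for each gene, the call ended under 18 for Cartpt, 18 for Mxra7, 11 for Ctxn3, 5 for Hkdc1 and 5 for Qrfpr. The mutant mean of Ctxn3 lay below the filter of 4, where log2 differences are compressed, so no fold is given. All 6 genes had every mutant array beyond every wild-type array.

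Genes next in line by p, not past the test, were Wnt7a, a secreted Wnt ligand (log2 difference 0.84, adjusted p = 0.090), Lrfn1 (0.64), the transcription kinase gene Cdk12 (0.72), Ovca2 (0.70), Tmem35b (0.51), Tifa (0.68) and the urea transporter gene Slc14a1 (0.77). In the other direction they were the cation channel gene Trpc5 (-0.80), the sialidase gene Neu2 (-0.51), Pgpep1 (-0.59), the calcium-binding protein gene Necab1 (-0.76), the ubiquitin-conjugating enzyme gene Ube2a (-0.44), Cdkl4 (-0.37) and the prostaglandin receptor gene Ptger3 (-0.89). For Wnt7a, 1 of 2 probe sets had this sign, for Cdk12 2 of 5 and for Pgpep1 2 of 3.

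By limma, 520 genes had an unadjusted p under 0.05 in adults, 394 of them higher and 126 lower, against 572 that chance gives. The median log2 difference over all genes was 0.031, and it became 0.0033 with quantile normalization over 12 arrays and -0.021 with median centring. The split into 394 and 126 was not recounted under those scalings. With the age pair as a block 3 genes were called, Kat6b, Hkdc1 and Cartpt. Leaving out 1 adult array left between 0 and 6 calls, with 0 without wild type 2 or mutant 1, and 1 without wild type 1 or mutant 2. Mutants 1 and 2 also had signs of lower RNA quality in the actin control (values below), and a part of RNA quality in these gene calls was not tested. Without embryonic wild type 1, wild type 3 or mutant 2, which share the estimate of the spread, 3 genes were called. The call of Qrfpr remained without wild types 1 and 3 and mutant 3 (in turn), and that of Hkdc1 without wild type 3, mutant 2 and mutant 3.

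**Figure D2:**
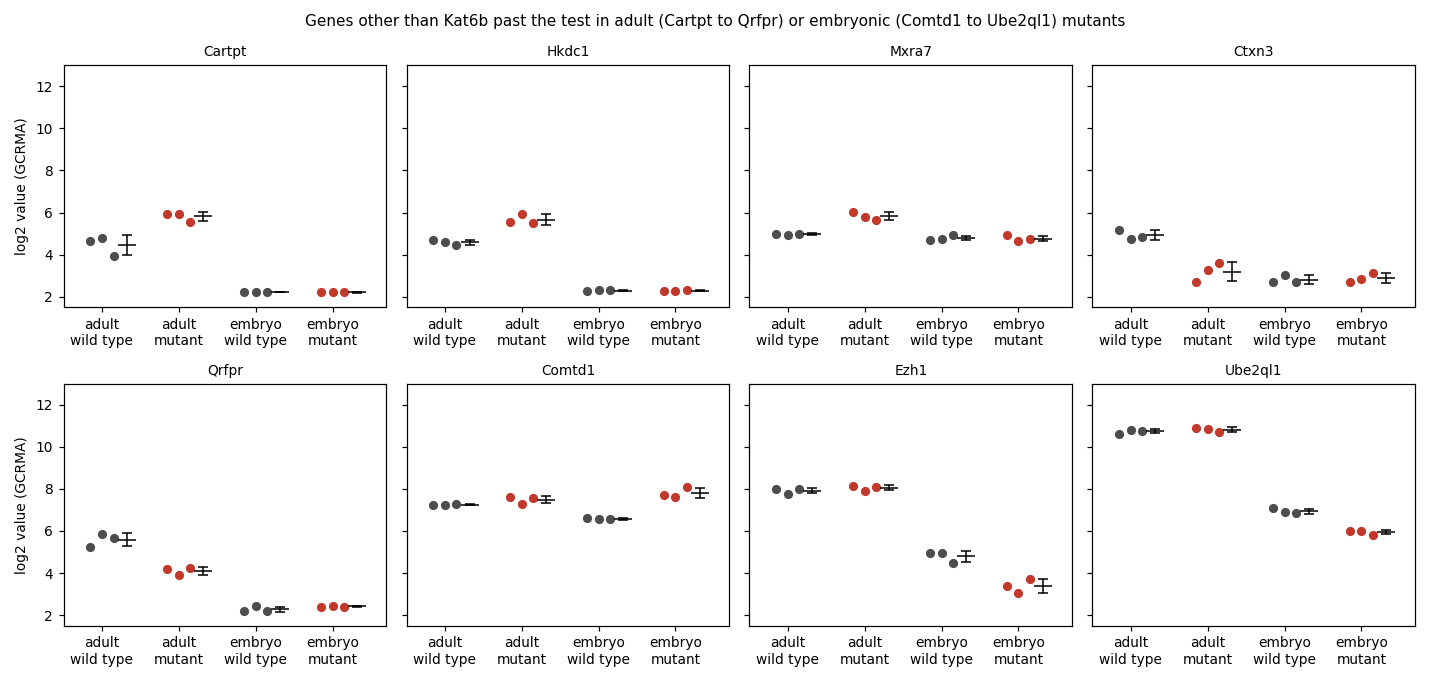
Log2 value (vertical axis) on each array (points) in the 4 groups (horizontal axis), with group mean and SD (bars), of the 8 genes other than Kat6b past the test in one stage. Cartpt and Hkdc1 are near the floor of 2.19 in every embryo.

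Genes of myelin and oligodendrocytes were lower together in adult mutants: 19 of 20 measured members had a negative difference, with a median of -0.30. No single member passed over all genes or when adjusted over the list alone. The members with the lowest p were Myrf, the regulator of myelin genes (log2 difference -0.38), Sox10 (-0.34) and the myelin protein gene Mal (-0.42). Camera gave an adjusted p of 1.57e-08, and adjusted p = 0.549 with an estimated correlation. The mean over the list was 9.04 ± 0.22 (n = 3) in wild types and 8.76 ± 0.18 (n = 3) in mutants, and mutant 2 (8.97) lay above wild type 2 (8.80), with an exact permutation p of 0.2. Oligodendrocyte precursor markers were not called (adjusted p = 0.503), and among them Tnr passed when adjusted over the list alone (log2 difference 0.41) and not over all genes.

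Genes of oxidative phosphorylation, chosen by name prefix, were slightly lower in adult mutants: 62 of 79 were negative, with a median of -0.05, and 0 members passed over all genes or adjusted over the list alone. Atp5c1 (-0.21, and positive without _s_at and _x_at probe sets) and Ndufb8 (-0.23) had the lowest p. Camera gave an adjusted p of 7.83e-05, and adjusted p = 0.899 with an estimated correlation. The mean over the list was 11.325 ± 0.024 (n = 3) in wild types and 11.282 ± 0.041 (n = 3) in mutants, with an exact permutation p of 0.2. Mutant 3 (11.327) lay within the wild-type range of 11.298 to 11.342. The call ended without mutant 2 (adjusted p = 0.059), which left 1 list called, and without mutant 3 there were 4. The mean difference of -0.043 became -0.026 without mutant 2, -0.066 without mutant 3 and -0.095 with arrays centred on their median. The 3 prime minus 5 prime difference of the actin control, a sign of RNA quality, was 1.91 on mutant 1 and 1.47 on mutant 2, against 1.06 to 1.13 on the other 4 adult arrays. That of the Gapdh control was 0.257 on mutant 1, against -0.154 to -0.059 on the other adult arrays.

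Other adult lists were not called. The mean and the median differed in sign for the KAT6, deep-layer, upper-layer, cell cycle, microglia, striatum and axon guidance lists. Of the 13 measured members of the KAT6 complexes and MYST family, Kat6b fell, and Brpf3, a scaffold of these complexes, passed only when adjusted over the list alone (log2 difference 0.69, adjusted p = 0.679 over all genes). Among 40 components of the RAS-MAPK pathway 28 were positive and 12 negative, with Fgfr1 at 0.44 (0.17 without _s_at and _x_at probe sets) and Egfr at -0.34 (-0.12 with the mean of its probe sets), and 0 passed either way. In the Wnt and Shh list Wnt7a alone passed when adjusted over the list alone. Endothelium and pericyte markers were positive in 17 of 22 (Tek 0.33, Pdgfrb 0.40) and cortical interneuron markers negative in 15 of 25 (Tac2 -0.45, and -0.29 without wild type 3, Lhx6 -0.38), both with adjusted p = 0.095. With the age pair as a block these lists were called, at adjusted p = 0.044 and 0.012, which made 4 lists in place of 2. With an estimated correlation, run without the block, adjusted p = 0.899 for each. Deep-layer neuron markers (Cplx3 -0.82, Fezf2 -0.39) and cell cycle genes (Rfc4 0.44, negative as a mean of its probe sets, Mcm7 0.37, Rrm1 0.81) had 0 members past either adjustment by limma. Cplx3 went to -0.49 without mutant 1, Rrm1 to 0.51 without wild type 2 and 0.14 with the mean of its probe sets, and Mcm7 to 0.093 without _s_at and _x_at probe sets. Ttr, the abundant transcript of choroid plexus, stood at 15.2 in adult mutant 3 against 6.78 to 9.18 in the other adults.

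In embryonic mutant telencephalon 4 genes changed, 1 upward and 3 downward. Besides Kat6b, Ezh1, a methyltransferase of Polycomb repressive complex 2, fell from 4.79 ± 0.26 to 3.40 ± 0.33 (n = 3 each, log2 difference -1.40, adjusted p = 0.021), and Ube2ql1, a ubiquitin-conjugating enzyme family gene, fell 1.99-fold from 6.94 to 5.95 (SE 0.11, adjusted p = 0.0066). Comtd1, a gene of the catechol-O-methyltransferase family, rose 2.35-fold from 6.57 to 7.80 (SE 0.13, adjusted p = 0.0066). The mutant mean of Ezh1 lay below the filter of 4 as well. Each had every mutant array beyond every wild-type array.

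Next by p and not past the test were the cytochrome gene Cyp2j9 (log2 difference 1.27, adjusted p = 0.071), the endothelial adhesion gene Pecam1 (0.73), Csdc2 (0.84), the glucose transporter gene Slc2a4 (0.87), Slc13a3 (1.15), P3h1 (0.67), Drc1 (1.03), Troap (0.95) and Gfap, the astrocyte filament gene, at 3.09 in wild types and 5.20 in mutants. Lower values were Jakmip1 (-1.83, adjusted p = 0.060), Lmo7 (-0.93), Fam122b (-0.85), Prkar1b, a subunit of protein kinase A (-0.91), Pm20d2 (-0.96), Unkl (-0.59) and the glutamate receptor gene Gria3 (-1.22). Probe sets disagreed in sign for Csdc2, Slc13a3, Jakmip1 and Prkar1b.

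By limma, 516 genes had an unadjusted p under 0.05 in embryos, 219 higher and 297 lower, where chance gives 572. With the parental cross as a block only Kat6b was called, and adjusted p was 0.060 for Comtd1, 0.057 for Ube2ql1 and 0.11 for Ezh1. Mutant 1 came from a later array set than the other 5 embryos. Without it, and so within the shared set, 8 genes were called, 3 of them among the 4. Without wild types 1, 2 and 3 in turn 13, 7 and 10 genes were called, and without mutant 2 there were 8. Dlx2, a transcription factor of the ventral telencephalon, stood at 9.04 and 8.43 in the 2 embryos of the first cross against 3.20 to 5.80 in the 4 of the second. Without both embryos of the first cross, an alternative chosen after seeing the data, 18 genes were called, 3 of them among the 4.

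**Figure D3:**
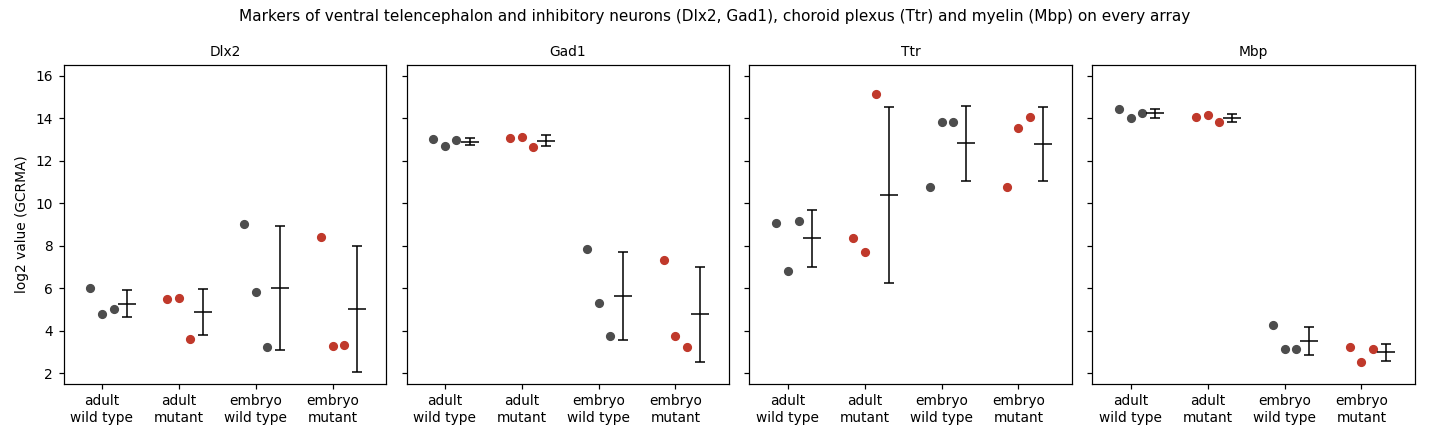
Log2 value (vertical axis) of Dlx2, Gad1, Ttr and Mbp on each array (points) in the 4 groups (horizontal axis), with group mean and SD (bars). Dlx2 is at 9.04 and 8.43 in replicate 1 of the embryonic wild types and mutants, and Ttr is at 15.2 in adult mutant replicate 3.

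In the embryonic mutants the oxidative phosphorylation list was called in the upward direction: 60 of 79 members were positive, with a median of 0.06 and 0 members past the test over all genes or adjusted over the list alone. Camera gave adjusted p = 0.037, and adjusted p = 0.814 with an estimated correlation. The call ended without wild type 1 (adjusted p = 0.171), mutant 2 (0.133) or mutant 3 (0.287), and without mutant 3 the mean difference went from 0.052 to 0.0015, so the shift rested on that array. The mean of the cortical hem and choroid plexus list was also highest on that array, at 6.68 against 5.76 to 6.26 in the other embryos, and a link was not tested. The oxidative phosphorylation call also ended with quantile normalization over all arrays (0.087) or within each stage (0.085), without _s_at and _x_at probe sets (0.074) and with array weights (0.095). The oxidative phosphorylation list mean was 10.85 ± 0.04 (n = 3) in wild types and 10.90 ± 0.09 (n = 3) in mutants, with an exact permutation p of 0.4.

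ERK feedback and target genes were positive in 12 of 17 (Etv5 0.81, and 0.54 without wild type 3) and were not called (adjusted p = 0.110), and axon guidance and adhesion genes were negative in 37 of 52 (Robo2 -0.42, Cntn1 -0.75, Pcdh8 -0.65; adjusted p = 0.129). Both were called with the parental cross as a block, each at adjusted p = 0.041, which made 3 lists in place of 1. With an estimated correlation, run without the block, adjusted p was 0.736 for each. Cntn1 went to -0.46 without mutant 1, -0.47 without wild type 2 and -0.31 with the mean of its probe sets. Mature excitatory neuron and synapse genes were negative in 23 of 31 (adjusted p = 0.129), and Gria3 among them passed when adjusted over the list alone and not over all genes. Gfap among astrocyte markers and Pecam1 among endothelial markers passed in the same way only. With the mean of a gene's probe sets Gria3 went from -1.22 to -0.66 and Gfap from 2.11 to 1.09. Of the KAT6 list only Kat6b passed either adjustment. Progenitor markers were near balance, with 17 of 32 radial glia genes positive (Lhx2 -0.37) and 25 of 43 cell cycle genes positive (Kif20a 0.29, Plk1 0.24, Tyms -0.65, and -0.39 without mutant 3), and by limma 0 members passed either adjustment. Microglia markers were positive in 16 of 18 (Csf1r 0.74, which was 0.47 without wild type 1 and 0.13 with the mean of its probe sets; list adjusted p = 0.110).

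**Figure D4:**
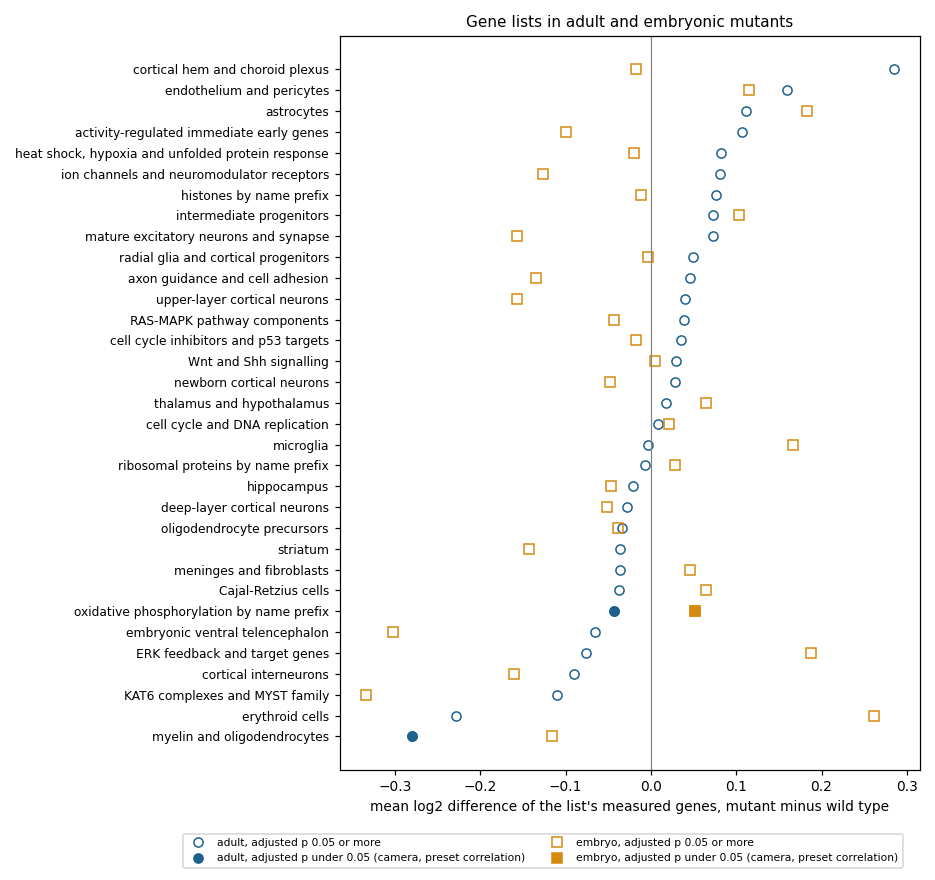
Mean log2 difference between mutants and wild types (horizontal axis) over the measured genes of each of 33 lists (vertical axis) in adults (circles) and embryos (squares). Filled symbols have an adjusted p under 0.05 by camera with the preset correlation: myelin and oxidative phosphorylation in adults and oxidative phosphorylation in embryos.

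The difference between the stages in the effect of the mutation was tested itself. Kat6b fell by less in adults than in embryos on the log2 scale (difference between the effects 1.84, 95% interval 0.92 to 2.76), with adjusted p = 0.528 over all genes. Tested with every probe set on its own, the difference passed for the second Kat6b probe set (2.42, adjusted p = 0.021), which is near the floor in adults. With the mean of a gene's probe sets Kat6b was the 1 gene called for this difference. On the main probe set the mutants stood at 7.11 in adults and 7.06 in embryos, and the wild types at 9.58 and 11.37. The stages thus differed in the wild-type mean and hardly in the mutant mean, though single embryonic mutants ran from 6.22 to 7.72. By limma 0 genes passed, 630 had an unadjusted p under 0.05 against 572 that chance gives, and 0 passed with the block. The genes with the lowest p, none past the test, were Ube2ql1 (1.07), Hkdc1 (1.08), Ezh1 (1.53), Wnt7a (1.11) and Ovca2 (1.06) in one direction. In the other they were Qrfpr (-1.62), Ctxn3 (-1.81), Comtd1 (-1.0), Pgpep1 (-0.87) and Cyp2j9 (-1.23). Adjusted p for these 10 genes ran from 0.128 to 0.475.

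Across genes, adult and embryonic differences were barely related (Pearson -0.04, Spearman -0.10, over genes that are not independent replicates). The comparisons share no arrays. Of the genes with an unadjusted p under 0.05 in each stage 31 were shared, where independence gives 23.4, with 13 of the same and 18 of opposite sign. Kat6b was the 1 gene called in both stages.

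Adult cortex and embryonic telencephalon of wild types differed in 9314 genes, 4396 higher and 4918 lower in adults, and 6432 of them by at least 2-fold. Adult cortex was higher in neuronal genes such as the calcium sensors Vsnl1 (log2 difference 11.25) and Hpcal4 (10.07), Thy1 (10.58), Rasgrf1 (9.72), Kalrn (9.61), Nrsn1 (9.44), Rgs4 (9.43) and Gda (9.42), and in the myelin gene Mbp (10.71) and the prostaglandin synthase gene Ptgds (10.20). With the mean of its probe sets Kalrn went to 2.89. Embryonic tissue was higher in the embryonic globins Hbb-y (-13.27), Hba-x (-10.77) and Hbb-bh1 (-10.69), in the proliferation genes Mki67 (-9.68), Top2a (-9.66), Ube2c (-9.65), Rrm2 (-9.58) and Mcm6 (-9.20), in the neurogenic factor Neurog2 (-9.66) and in Hmga2 (-9.36). In the cell cycle list all 43 members were lower in adults, and in the myelin list all 20 were higher. Camera called 18 lists, 11 higher and 7 lower, of which 6 held with an estimated correlation. Stage, dissected region and array set cannot be told apart in this comparison.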

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

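The tests of white matter content and RNA quality below were chosen after the results they bear on had been seen, and sex as a covariate and the fit without the first cross were alternatives added after the data had been seen.

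Kat6b, by its own interval, and 3 gene lists, by camera with the preset correlation, stand here for an effect of the mutation that appeared to differ between adults and embryos. Kat6b fell by less in adults, by a log2 difference of 1.84 (95% interval 0.92 to 2.76 for this gene alone, limma adjusted p = 0.528 over all genes). Its mutants stood at 7.11 in adults and 7.06 in embryos, against wild types at 9.58 and 11.37. The difference thus lay in the wild-type means, though single embryonic mutants ran from 6.22 to 7.72. Signal left in the mutants was 18.1% of wild type in adults and 5.04% in embryos. Whether the mutant level is background or remaining transcript was not determined, so the difference does not by itself show a weaker effect of the mutation in adults. The mean difference between the adult and the embryonic effect was -0.26 over 17 ERK feedback and target genes (camera adjusted p = 0.018), -0.16 over 20 myelin genes (adjusted p = 0.048) and -0.095 over 79 oxidative phosphorylation genes (adjusted p = 7.8e-06). With an estimated correlation adjusted p was 0.934 for each of the 3 lists. The count of 3 lists became 1 without embryonic wild type 3, without embryonic mutant 2 or without a filter, 9 without embryonic wild type 1, 7 with array weights, 7 without _s_at and _x_at probe sets, 8 without the first cross, and 0 with fry. The ERK call ended without adult wild type 2, adult mutant 3, embryonic wild type 3 or embryonic mutant 2 (adjusted p of 0.105 to 0.216), and without a filter on low values (0.061). The myelin call ended under 19 of 28 alternatives, among them 8 of the 12 arrays left out in turn (adjusted p of 0.067 to 0.399), each scaling, and the replicate block (0.080). Leaving out 1 array gave mean differences of -0.377 to -0.155 for ERK feedback, -0.288 to -0.081 for myelin and -0.137 to -0.044 for oxidative phosphorylation, the last at -0.044 without embryonic mutant 3.

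Signal also appeared in probe sets outside the named genes. Of 3557 tested probe sets with several or no listed genes, 2 passed the test in adult mutants, 8 in embryonic mutants and 4 for the difference between stages. Of these, 2 fell in the mutants of both stages. The first had a log2 difference of -2.5 in adults (5.92 ± 0.39 to 3.42 ± 0.14, n = 3 each) and -5.44 in embryos (9.13 ± 0.13 to 3.69 ± 0.14), and the second -2.03 in adults and -5.40 in embryos. Neither is paired with a gene in the annotation used here.

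Myelin genes had a mean log2 difference of -0.28 in adult mutants, called with the preset correlation and not with an estimated one (adjusted p = 0.549). Variation in the white matter of the dissected piece remains open: the list mean spanned 0.414 among the 3 wild types, more than the difference between the genotypes, and the genotypes overlapped. RNA quality remains open too: with the actin difference as a covariate 117% of the shift was kept, but at -0.33 with an SE of 0.18 it lay within 2 SE of 0. Adult mutant 3, whose actin difference lay within the wild-type range, differed from the wild types by -0.41, a comparison tried first and replaced, since 1 array decides nothing. An effect of the genotype on oligodendrocytes stays open.

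Oxidative phosphorylation genes were called lower in adult and higher in embryonic mutants, by small amounts (in embryos a mean of 0.0015 without mutant 3), with the preset correlation and not with an estimated one (adjusted p = 0.899 and 0.814). A residual of the normalization that depends on signal level stays open. The list median lay at the 0.02 percentile of 10000 random lists matched on mean expression in adults and at the 100 percentile in embryos. Matching used the mean over all 12 arrays, not the level within a stage, and the random lists held unrelated genes. ERK feedback genes, not called in either stage, lay at the 0.1 and 99.3 percentiles, so an extreme percentile does not decide this. The embryonic call ended with either quantile normalization, and the adult mean went from -0.043 to -0.095 with median centring. RNA quality remains open for the adult shift, since with the actin difference as a covariate 31.5% of it was kept (-0.01, SE 0.06). An effect of the genotype stays open in both stages.

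Comtd1, Ezh1 and Ube2ql1, the genes besides Kat6b past the test in embryos, were set against the unequal sex of the embryos and the later array set of mutant 1. With sex as a covariate at least 88.8% of each log2 change was kept (Ezh1 -1.24, SE 0.13), and all 3 stayed past the test. Without mutant 1 at least 100.2% was kept, though Ezh1 no longer passed (adjusted p = 0.060 with fewer arrays), which is 1 of 11 alternatives among 27 that ended its call. Both tables argue against these as the whole source of the changes. The parental cross as a block, which cannot change these log2 values since each cross holds as many mutants as wild types, gave an SE of 0.14 in place of 0.13 for Comtd1, 0.19 in place of 0.18 for Ezh1 and 0.10 in place of 0.11 for Ube2ql1, and the 3 calls ended with 5 in place of 8 residual degrees of freedom. A genotype effect on these genes stays open as a hypothesis.

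Other splits of the arrays were tested for each count of genes. For the 6 adult arrays the 10 splits are too few for a share under 0.05. The real split called 6 genes, 1 split of the 10 (the real one) gave as many, and the highest other gave 2. For the 6 embryos 7 of 10 splits gave at least the 4 genes of the real one, and the highest other gave 29. A share of 0.05 or more had been set beforehand to mean that grouping alone can give such a count. With 10 splits no share under 0.05 was possible, so that rule was met in advance and decides nothing. Several other groupings of the same embryos gave at least as many genes, among them groupings tied to cross or sex. The embryonic count by itself therefore does not set the genotypes apart. The 4 splits that kept both embryos of the first cross together called 7 to 29 genes, up to several times the real count, which points to a structure of the samples by cross. The 5 other splits that part them, as the real one does, called 0 to 10, and 2 of them gave at least as many as the real one. Of these 2, the split with 10 set the 3 embryos with Xist against the 3 with Eif2s3y, so it parted the sexes. The other called 5. With the cross as a block the real split called 1 gene. For the stages 1 split of 10 (the real one) gave as many as 9314 genes and the highest other gave 0, with too few splits for a share under 0.05. For the difference between stages 100 of 100 drawn splits gave at least the 0 genes of the real one, as any split must, and the highest other gave 9, so this count decides nothing.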

How the results depend on the processing

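Sex as a covariate and the fit without both embryos of the first cross were chosen after the data had been seen. The count between the stages stayed within 1.5 times of 9314 under each of its 22 alternatives (8438 to 9784). Kat6b fell under each alternative tried in both stages, with log2 differences of -2.59 to -2.37 in adults and -4.64 to -3.89 in embryos, and its adjusted p ran up to 0.15 in adults and 0.49 in embryos. The settings that change which probe sets are tested kept these differences, except for -1.43 and -3.56 with the mean of its probe sets, and without a filter the adult call was lost (adjusted p = 0.10). With only the arrays of the stage, which leaves 4 residual degrees of freedom, Kat6b no longer passed, at -2.47 (adjusted p = 0.071) in adults and -4.31 (adjusted p = 0.486) in embryos, and 0 genes were called in adults and 0 in embryos. Of 3686 alternative values for the 146 other reported values, 3508 kept direction and side of the threshold, 114 no longer passed, 56 newly passed and 8 reversed. Most of the 146 were values of genes not past the test, which had no call to lose, so the total says little about the calls. All 114 losses fell on called lists and on genes called in a mutant contrast. Among them were 18 of 24 alternatives for Cartpt and 19 of 28 for the myelin list between stages. Among the 146 are 140 values of genes, of which 53 moved by over 1.5 times under at least 1 alternative, 29 of them with 1 array left out and 34 with the mean of probe sets. For what follows the cause was not tested unless given. The 6 genes of adults became 1 with the stricter filter, under which genes with low values were not tested, 3 with the replicate block and 3 with the trend and robust variance model. The 3 higher of 6 became 1 of 4 with median centring or quantile normalization over 12 arrays, and 2 of 5 with quantile normalization within each stage. The 4 genes of embryos became 8 with the stricter filter, 12 with every probe set, 1 with the replicate block, 9 with the pair or cross as a random block, 42 with array weights and 18 without the first cross. For the difference between stages the count of 0 became 1 without a filter, 3 with every probe set, 1 (Kat6b) with the mean of a gene's probe sets and 7 with array weights. The 2 lists of adults became 4 with the block, and 0 with an estimated correlation and 0 with fry. The 1 list of embryos became 2 with the mean of probe sets, 0 without _s_at and _x_at probe sets, 0 with quantile normalization over 12 arrays and 0 within each stage, 3 with the block, 3 with array weights (oxidative phosphorylation not among them), 2 with sex as a covariate, 9 without the first cross, and 0 with an estimated correlation and 0 with fry. The block changed no other count by over 1.5 times. Without the first cross, which for adults alters only the shared estimate of the spread, adults had 2 genes (Kat6b and Qrfpr) and 4 lists. Leaving out 1 array at a time, which removes samples, gave 0 to 6 genes in adults, 3 to 13 in embryos, 0 to 1 for the difference and 8964 to 9428 between stages, 1 to 4 lists in adults and 0 to 8 in embryos, and Kat6b at -2.59 to -2.37 and -4.64 to -3.89. Pgpep1 in adults reversed to 0.077 with the stricter filter. With the mean of probe sets adult Rfc4 reversed to -0.10, Nos1 to 0.041 and Egln3 to 0.0085. Without _s_at and _x_at probe sets adult Atp5c1 reversed to 0.14, and embryonic Csdc2 to -0.12, Slc13a3 to -0.063 and Jakmip1 to 0.15, since other probe sets then stood for these genes. Changes of genes near the floor of 2.19 are compressed, which limits what low signals can show.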

Other observations

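The test of the genes nearest to Kat6b, the comparison without the first cross and the splits that part it were chosen after the values had been seen.

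Without the embryos of the first cross the embryonic contrast rested on 2 embryos a genotype. Of these 4, wild type 2 kept more ventral signal (Dlx2 5.80 and Gad1 5.28, against at most 3.31 and 3.74 in the other 3), so a difference in tissue ran along with genotype. In this contrast 9 lists were called by camera with the preset correlation, which with an estimated one was not run for this comparison. Lower in the mutants were mature excitatory neurons and synapse (mean log2 difference -0.22, adjusted p = 0.00155), ion channels and neuromodulator receptors (-0.18), axon guidance and adhesion (-0.17), upper-layer neurons (-0.22) and newborn cortical neurons (-0.10). ERK feedback genes (0.34), Cajal-Retzius markers (0.25), erythroid genes (0.51) and oxidative phosphorylation genes (0.07) were higher. Among the 18 genes called were Nexmif, Rbfox1, Lin7a, Flt4 and Klf9, picked here after their values were seen.

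A hypothesis of delayed neuronal maturation was tested on all arrays. Across genes the embryonic mutant difference correlated at -0.077 with the difference between adult wild types and the mean of all 6 embryos, in the direction that a delay may give. Both embryonic genotypes enter that mean equally, and the mean correlation over the ordered splits was 0. Among the other of 20 ordered splits of the 6 embryos the lowest was -0.080, and their SD was 0.053, so the relation cannot be told apart from the spread among embryos. Of the 12 ordered splits that part the first cross, 2 gave a value as low as the real one (itself and the one at -0.080). A lower split had been set beforehand as evidence against a delay, but a gap this small beside that SD decides nothing with 3 embryos against 3.

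Comtd1 lies 3 measured genes from Kat6b in the gene order of assembly GRCm38.p6. A hypothesis of a local effect of the insertion on its neighbours was tested on the 20 nearest measured genes before their values were seen. Their median absolute log2 difference lay at the 92.5 percentile of 10000 windows of neighbouring genes in adults and at the 40.8 percentile in embryos. The embryonic value argues against an effect that reaches most of them at that stage. The adult value (0.143, against 0.099 for the median window) lay below the cut-off set beforehand but was high, so it decides nothing. A median over 20 genes is blind to an effect on the nearest few. The other 5 genes within 3 measured genes of Kat6b had a mean embryonic log2 difference of 0.25, at the 99.2 percentile, with Samd8 at 0.61, Adk at 0.36, Vdac2 at 0.20, Ap3m1 at 0.12 and Vcl at -0.05. In adults their mean was -0.072, with Samd8 at 0.24, Adk at 0.082, Vdac2 at -0.069, Ap3m1 at -0.63 and Vcl at 0.019, so the upward mean was not seen there. None of these 5 passed the test over all genes as reported (Samd8 adjusted p = 0.25), and Samd8 was called with array weights. Whether a local effect of the gene trap contributes to the rise of Comtd1 stays open, as a hypothesis found and tested on the same data and seen in 1 stage only.

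The 2 unnamed probe sets that fell in both stages may report transcripts of the targeted gene. Within groups, Kat6b ranked 656 of 11449 genes by its correlation with the first of these probe sets and 7022 with the second. With 3 arrays a group and mutant SDs of 0.04 to 0.14 there was little variation to rank on, so the test left this open. Over all arrays they correlated with Kat6b at 0.97 and 0.95, though they were picked for falling in both stages. Like Kat6b, both were higher in embryonic than in adult wild types (9.13 against 5.92, and 9.01 against 5.59).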
